A study of Mus musculus with 6 samples.

How the data were processed

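Menin ChIP-seq and input libraries came from wild-type C57BL/6 mouse Th2 cells at 2 culture stages. Per the labels' protocols, CD4 T cells of the spleen were kept for 5 days with IL-2 (15 ng/ml) and IL-4 (10 ng/ml), and the other stage added 2 days without cytokines and 5 days of restimulation through the T cell receptor with IL-2 and antibodies against IL-4. The same labels call that stage 3 weeks old, a name kept here although the stated days are fewer. Nuclei were sonicated, Menin was precipitated with an anti-Menin antibody, and libraries were made with a NEBNext ChIP-seq kit and 15 cycles of PCR and sequenced on an Illumina HiSeq1500, per the labels.

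Each of the 6 deposited files lists aligned reads. Its count column is 1 in every line, so the unit is an unscaled count of reads as the authors deposited it. The other columns give positions, and every read spans 120 bp in the deposited files. The genome build mm10, CASAVA and Bowtie 0.12.8 are named per the submitters' processing notes, without their roles. Read filters and the extension to 120 bp were not given in the sources used here. PCR copies were kept in the deposited files, and they made up 17.5% and 22.5% of reads in the 5-day Menin runs, 38.6% and 47.9% in the 3-week Menin runs, 17.2% in the 5-day input and 20.5% in the 3-week input.

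The 2 Menin samples of a stage shared far more fragment positions than other pairs and were treated as 2 sequencing runs of 1 library. They were merged, each position and strand was counted once, and inputs were treated alike. The plan written before the data were examined had these samples as replicates, reads as deposited, edgeR's quasi-likelihood test for enrichment and change, and camera, fry and Fisher's exact test for gene lists. Counted as 1 library per stage, the samples leave those tests no spread between replicates. Rules of size with counting intervals took the place of edgeR, percentiles among random lists took the place of the list tests, and edgeR and DESeq2 on the runs were kept as alternatives. Camera and fry, with a preset or an estimated correlation, were left out for that reason. No p-value across genes is given.

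Gene positions came from a table of RefSeq genes on GRCm38.p6, the assembly also named mm10, which matched 479 of 480 listed gene symbols, with Mina found under the name Riox2 and Trdc unmatched. The table gives no strand or transcripts, and no genome sequence was used here. For each of 21631 protein-coding genes on the autosomes and X, Menin fragments were therefore counted in a 2-kb window at either end of the gene, and the end with more was kept. Counting at the most upstream start site, also planned, was not run, because it needs strand. Library sizes were scaled by TMM factors (edgeR) over 10-kb bins, with the 5-day input as reference library.

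A gene end was tested when at least 2 libraries had 10 or more fragments there (21451 genes). It was called enriched at a fold over input of 2 or more with the lower bound of the exact Clopper-Pearson 95% interval above 1, using a pseudocount of 0.5 for log2 folds. Change from 5 days to 3 weeks was assessed at 7243 gene ends whose log2 fold over input, averaged over the stages, was 1 or more, and called at 2-fold or more with an interval excluding 0. Median fragments per tested gene end were 105 in 5-day Menin, 40 in 3-week Menin and 29 in each input, and 682 tested ends had 3 or fewer fragments in the 3-week input. Reads without molecular identifiers are not independent molecules, so the intervals cover counting error only. Whole gene spans with 5 or more enriched windows were compared in the same way.

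Windows of 1 kb were called enriched by a Poisson test against the larger of the library's mean and the scaled input, with a Benjamini-Hochberg adjusted p under 0.001 and 3-fold or more. The 25788 windows with over 5 times the median input were left out. Windows enriched in either stage were compared by the rule used at gene ends.

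For 17 gene lists written before the data were examined, the share of enriched gene ends was placed among 10000 random lists of the same size. The median change, relative to that of all gene ends or spans, was placed among 10000 random lists matched on Menin signal over 20 levels. Lists with fewer than 5 members in a comparison were given no median. Percentiles describe these libraries, since genes are not replicates.

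The rule for named genes was fixed before the data were examined. It took the 12 highest folds per stage among gene ends enriched in both, up to 12 changed gene ends per direction by size with both runs of one stage beyond both of the other, 14 genes fixed by name (Gata3, Il4, Il5, Il13, Il1rl1, Bach2, Ifng, Tbx21, Cdkn2a, Cdkn2c, Cdkn1b, Hoxa9, Meis1 and Men1), the members of each list with extreme values, and for windows the 5 longest runs and the 5 most changed per direction. Genes known only by Gm, Rik or LOC symbols were counted but not named, and a few genes that the rule takes are not reported here. The planned lowest fold over the 2 samples of a stage became the fold of the merged library. As the runs were counted as 1 library, their concordance was not taken as a replicate check. The Poisson test of windows, planned on each sample, was made on the merged library. Changed gene spans and members of lists beyond the extremes were named after their values were seen.

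The rules for gene ends, spans, 5-day windows and lists were tested on simulated data. With 200 of 21451 genes enriched at both ends, the rule over input called 96% (5-day) and 97% (3-week) of those at 3-fold, all at 6-fold, and 71 and 240 gene ends without enrichment. Both simulated inputs were drawn from the pooled rate of the 2 inputs, so the unevenness of the 3-week input was not simulated. The simulated 3-week values therefore do not cover errors that come from gaps in that input. With 200 of 7243 gene ends changed, the rule at gene ends called 92% of those raised 2.5-fold, 86% of those lowered to 0.4, all of those changed 4-fold or to 0.25, and 11 unchanged ends. With 200 of 5123 gene spans changed by the same folds, all were called, and 0 unchanged spans. In both simulations of change the stages differed only by the set folds and counting error. They do not measure false calls from other differences between libraries, and on spans with many fragments counting error alone hardly reaches 2-fold. Of simulated windows raised 6-fold, 98.5% were called, and 0 of the background windows. Menin and input had the same background in that simulation, so the 0 does not measure false calls where their backgrounds differ. On the same 7243 gene ends edgeR called 98% at 2.5-fold and DESeq2 93%, with 10 and 0 unchanged ends. The runs of that simulation were drawn independently and without PCR copies. Its values therefore do not measure false calls on the real runs, which share many fragments. Alternatives were scaling by total fragments or on gene ends, copies counted, 1-kb windows at gene ends, other thresholds and filters, each run left out, the replicate number as a block and input-adjusted change. Added after the data were seen were the 5-day input for both stages, thinning to equal TMM-scaled depth, changes relative to the median, gene spans, lists over all gene ends and edgeR without the block on runs. Work was done in Python 3.11.15 (NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Matplotlib 3.10.9) and R 4.3.3 (edgeR 4.0.16, DESeq2 1.42.0).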

Results

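Binding of Menin, a scaffold protein of Trithorax group histone methyltransferase complexes encoded by Men1, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse Th2 cells, the helper T cells that make IL-4, IL-5 and IL-13. Splenic CD4 T cells of wild-type C57BL/6 mice were cultured with IL-2 and IL-4 and taken after 5 days, or taken from cultures labelled as 3 weeks old whose protocol describes 5 days of culture, 2 days of rest and 5 days of restimulation. Each stage had 2 deposited Menin samples and 1 input, which is sonicated DNA taken before immunoprecipitation. The 5-day Menin samples held 40747606 and 57043000 reads, the 3-week Menin samples 30615096 and 43589557, the 5-day input 31684993 and the 3-week input 22174783.

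The 2 Menin samples of a stage shared many fragments. Of the distinct fragment positions of the first sample, 36.5% in 5-day and 72.8% in 3-week cells occurred at the same base and strand in the second, whereas pairs of libraries from different stages or antibodies shared 0.74% to 2.0% of the smaller library's positions. Fragment counts at gene ends differed between the 2 samples of a stage by less than the sampling noise, with a mean chi-square of 0.696 in 5-day and 0.370 in 3-week cells where sampling alone gives 1, and of 2.63 between the stages. They were therefore counted as 1 sample per stage (n = 1, no replicate check), with each position counted once. This left 65531701 distinct Menin fragments from 5-day cells and 27824394 from 3-week cells. All intervals given are exact (Clopper-Pearson) 95% intervals and cover counting error only, and every difference between stages compares these libraries.

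**Figure D1:**
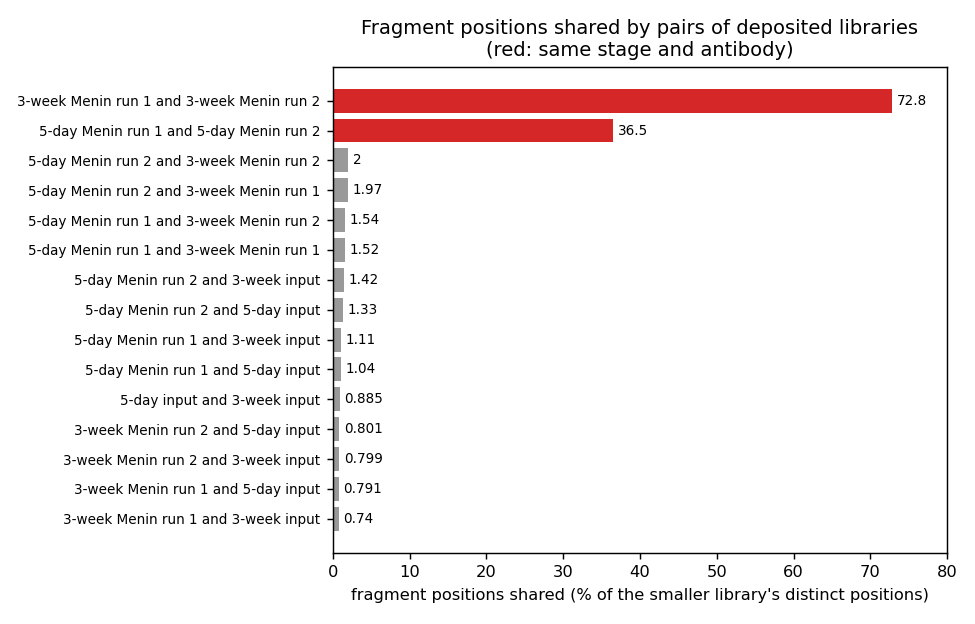
Fragment positions found in both libraries of a pair, as a percentage of the distinct positions of the smaller library (horizontal axis), for all pairs of the 6 deposited libraries. Red bars mark pairs of Menin runs from the same stage, at 72.8% and 36.5%, and grey bars mark all other pairs, at 2.0% or less.

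In 5-day Th2 cells, Menin was enriched at one end of 10231 of 21451 protein-coding genes (47.7%), at a fold over input of 2 or more. Among gene ends enriched in both stages, the largest 5-day folds were at Cdkn1b and Plgrkt. Cdkn1b, which encodes the cyclin-dependent kinase inhibitor p27, had a log2 fold of 4.33 (interval 3.80 to 4.98), and Plgrkt also had 4.33 (3.79 to 4.99). Other high folds were at Isoc1 (log2 fold 4.22), Lpar6 (4.20), Herc6 (4.14), Parp14 (4.04), Cenpj (3.99), Xrn1 (3.96), Ranbp6 (3.94), Irgm1 (3.93) and Dmac1 (3.90). Of these, Herc6, Parp14 and Irgm1 are interferon-responsive genes. Gata3, the transcription factor that directs Th2 differentiation, had a log2 fold of 3.16 (2.61 to 3.83) at its end on chromosome 2 at position 9887953 of mm10.

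Among the cytokine genes of 5-day cells, Il5 (log2 fold 1.76, interval 1.22 to 2.39), Il4 (1.46, 1.01 to 1.97) and Il13 (1.15, 0.66 to 1.69) were enriched. Ifng (0.55, -0.09 to 1.26), the cytokine of Th1 cells, and Il1rl1 (-0.05, -0.63 to 0.56), which encodes the IL-33 receptor, were not. Tbx21, the Th1 transcription factor, was enriched at 2.28 (1.83 to 2.80). The naive and memory cell repressor gene Bach2 had 1.94 (1.45 to 2.49), Cdkn2c 3.61 (3.04 to 4.29) and Cdkn2a 1.59 (1.08 to 2.17). Men1 had 1.41 (0.93 to 1.96) in a window that also held an end of another protein-coding gene, so this signal cannot be assigned to Men1 alone. Hoxa9 (0.51, -0.06 to 1.14) and Meis1 (0.43, -0.36 to 1.33), known targets of Menin in leukaemia, did not pass. Because the annotation gives no strand, the end with more Menin fragments stood for the promoter, and it need not be the start of the gene. At the other end too, 4445 enriched genes (43.4%) were enriched. The windows of 2720 enriched gene ends also held an end of another protein-coding gene.

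In 3-week Th2 cells, Menin was enriched at 4625 gene ends (21.6%) over the input of that stage, and 3620 of them were also enriched in 5-day cells. Gata3 (log2 fold 2.15, interval 1.65 to 2.73), Il4 (1.21, 0.61 to 1.88), Il5 (1.36, 0.76 to 2.03), Cdkn2c (3.51, 2.92 to 4.23) and Cdkn1b (6.76, 5.22 to 10.13) were among them. Il13 (-0.07, -0.58 to 0.45), Bach2 (0.34, -0.26 to 0.98), Tbx21 (0.53, 0.06 to 1.03) and Men1 (0.28, -0.34 to 0.95) were not. Among gene ends enriched in both stages, the 12 highest 3-week folds were at Ranbp6, Cdkn1b, Slc16a4, Cd200r4, Vmp1, Tmem255a, Slc18a2, Lpar6, Orc4, Gimap8, Nexn and Tex12. At each of these gene ends the 3-week input held 5 fragments or fewer. Ranbp6, for example, had 279 Menin fragments and 0 input fragments.

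The 3-week input was uneven, with 0 fragments in 7.30% of 1-kb windows against 0.240% in the 5-day input, so folds over it carry its gaps. With the 5-day input used for both stages, a comparison chosen after the data were seen, 8621 gene ends (40.2%) were enriched in 3-week cells, and 8041 of them (93.3%) were enriched in 5-day cells, where 47.7% of all gene ends were. Independent lists of these sizes would share 4112, and simulated libraries without enrichment over the same input shared 28 calls (of 99 and 105), so part of the overlap may come from the shared input. Over that input Bach2 (log2 fold 1.06), Tbx21 (1.71) and Il13 (1.16) passed in 3-week cells too, and Men1 (0.81) did not. Across gene ends, which are not independent replicates, the depth-scaled log2 Menin signals of the 2 stages correlated with Pearson's r = 0.925. Their log2 folds correlated with r = 0.523 over each stage's own input, and with r = 0.881 over the 5-day input that both then share.

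Gene groups fixed beforehand differed in how many of their members carried Menin in 5-day cells. All 56 ribosomal protein genes were enriched, as were 31 of 32 genes of T cell receptor signalling (Ptprc log2 fold 3.08, Cd4 2.98), 31 of 32 cell cycle genes (Aurkb 3.10, Top2a 3.05, Pcna 3.02) and 26 of 27 naive and memory T cell genes (S1pr1 3.15, Cd27 3.13, Cd28 3.11). Enrichment also reached 21 of 22 apoptosis and survival genes (Cflar 2.93, Mcl1 2.90), 27 of 30 Trithorax and MLL complex genes (Kdm6a 3.13, Mllt3 2.62), 25 of 30 Polycomb genes (Aebp2 2.90, Kdm2b 2.77), 23 of 27 Th2 transcription factors (Gata3 3.16, Ikzf1 3.07) and 18 of 26 Th2 cytokine and effector genes (Ccr8 2.93, Rad50 2.72). The shares of these 9 groups lay in the highest 2.5% of 10000 random lists of the same size.

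The shares of 5 other groups lay inside the middle 95% of random lists, and those of 3 lay below it. Enriched members numbered 18 of 29 among Th1 and cytotoxic genes (percentile 93.4; Il12rb2 3.03), 15 of 27 among Th17, Tfh and Treg genes (78.9; Sh2d1a 3.67, Ctla4 2.77), 9 of 27 among inflammatory and secreted factors of senescence (7.23; Lmnb1 2.79), 5 of 15 among B cell markers (14.2; Cd79a 1.59) and 3 of 14 among CD8 T, NK and innate lymphoid cell markers (2.71; Klrk1 2.26). Below the 2.5th percentile lay the Hox genes and other known Menin and MLL targets, with 10 of 35 (percentile 1.34), myeloid cell markers, with 5 of 20 (2.19; Cebpb 2.10), and genes of liver, muscle, neuron and epithelium, with 3 of 30 (0). In 3-week cells over their own input, 5 groups lay in the highest 2.5%: cell cycle genes (19 of 32 enriched), T cell receptor signalling (14 of 32), Th2 cytokines and effectors (13 of 26), Th1 and cytotoxic genes (12 of 29) and ribosomal proteins (22 of 56). Over the 5-day input 10 groups did, and enriched members numbered 22 of 30 Trithorax and MLL complex genes (5 over their own input), 22 of 30 Polycomb genes (10) and 17 of 27 naive and memory T cell genes (8).

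Menin-enriched windows formed long unbroken runs over some genes. In 5-day cells the longest runs of enriched 1-kb windows included those across Elf1 and Wbp4 (96 kb, chromosome 14, 79469001 to 79565000), Pde3b (85 kb), Satb1 (79 kb) and Ptprc (74 kb), which encodes CD45. In 3-week cells they included those across Ptprc (70 kb), Smc4 and Trim59 (39 kb), Fyb (36 kb), Satb1 (35 kb) and Ms4a6c (35 kb). Enriched windows numbered 84943 in 5-day cells (3.38% of 2509906) and 57294 in 3-week cells (2.28%), and 40803 were enriched in both, against 1939 shared by chance. The 3-week calls rest on the uneven 3-week input, and the signal in fixed windows differed less, with 17.3% of 5-day and 15.2% of 3-week Menin fragments in the 5-day windows, and 11.3% and 11.9% in the 3-week windows. Most lay inside genes (62.8% and 67.8%, against 43.0% of all windows), and 19.1% and 14.9% lay at protein-coding gene ends (4.26% of all windows). With 5-day fragments thinned to a fraction of 0.459, which matches the TMM-scaled library sizes and not the raw fragment numbers, 86366 windows were enriched in 5-day cells.

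At the Gata3 and Th2 cytokine loci, signals were compared as sums and by window. Over Gata3 and 10 kb on each side (chromosome 2, 9847078 to 9897953), 32 of 48 windows were enriched in 5-day cells and 26 in 3-week cells, with a log2 change of the summed signal from 5 days to 3 weeks of -0.09 (interval -0.15 to -0.03). Of 34 windows enriched there in either stage, 9 were higher in 3-week cells and 11 lower with an interval excluding 0, and 1 rose past 2-fold. Over the Th2 cytokine locus from Il4 through Il13 and Rad50 to Il5 (chromosome 11, 53602460 to 53735103), 72 and 46 of 128 windows were enriched, 31 of them in both, with a log2 change of the sum of 0.01 (-0.04 to 0.05). Of 87 windows enriched in either stage, 11 were higher and 7 lower with an interval excluding 0, and 1 fell past 2-fold. The Il4 span went from 5 enriched windows to 0, with a log2 change of -0.30 (-0.49 to -0.11), or -0.13 (-0.32 to 0.06) relative to the median of all spans. In both stages the highest signal there lay around the end of Rad50 nearest to Il5. Around Tbx21, 19 windows were enriched at 5 days and 8 at 3 weeks, with a log2 change of -0.57 (-0.66 to -0.48).

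**Figure D2:**
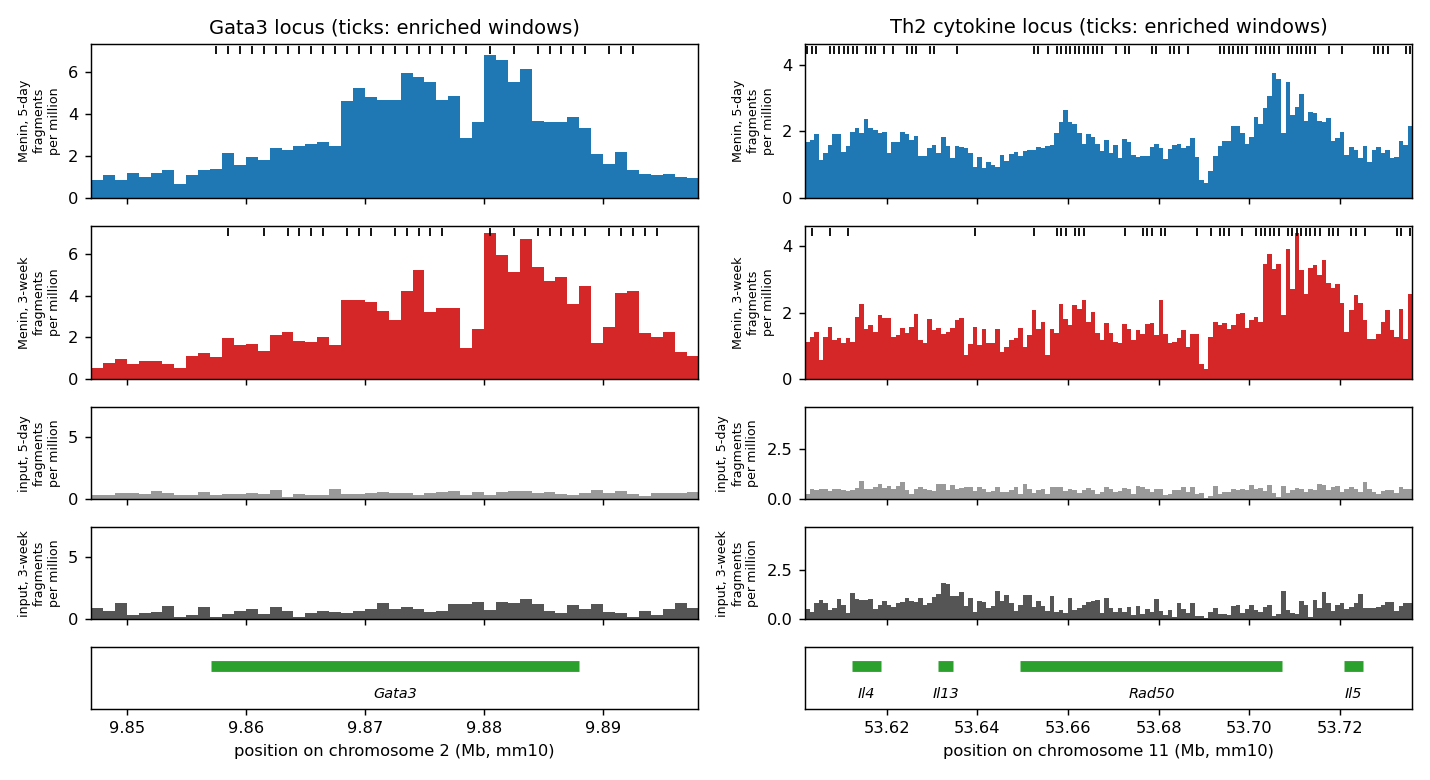
Distinct Menin and input fragments in 1-kb windows, scaled to the same library depth (vertical axes) along the Gata3 locus on chromosome 2 and the Th2 cytokine locus on chromosome 11 (horizontal axes, Mb, mm10), with gene spans in green and ticks above enriched windows. At Gata3, 32 windows were enriched at 5 days and 26 at 3 weeks, and at the cytokine locus 72 and 46.

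Other loci fixed beforehand differed from these. Around Cdkn2a, which encodes the inhibitors p16 and p19 and marks senescence, 5 windows were enriched at 5 days and 11 at 3 weeks, with a log2 change of 0.75 (0.65 to 0.85). Cdkn2c (22 and 23 windows, log2 change 0.13) and Cdkn1b (21 and 20 windows, -0.16) carried Menin at both stages. Around Men1, 2 windows were enriched at 5 days and 0 at 3 weeks. No window was enriched at either stage around Ifng, Il1rl1, Meis1 or the Hoxa cluster.

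The comparison of 3-week with 5-day cells asks where Menin signal differs between the stages. Per the labels, the stages differ in time in culture, in rest and restimulation through the T cell receptor, and in IL-4 against antibodies to IL-4. These differences cannot be told apart here. Menin was lower in 3-week cells at the ends of genes that include Art2b and Slamf6, which encode surface proteins of T cells. Art2b fell from 546 to 76 fragments (log2 change -1.71, interval -2.09 to -1.37) and Slamf6 from 337 to 56 (-1.46, -1.90 to -1.05). The log2 changes are scaled for library size, whereas the fragment counts are not, and the 3-week library was smaller. Slc14a1 (-1.59), Fam240a (-1.56), Calhm6 (-1.50), Txk (-1.44), H2-DMa (-1.41), Tmed8 (-1.37), Chrna9 (-1.36), Tmem154 (-1.36) and, on few fragments, Ptchd4 (32 to 4; -1.73) fell as well. Ptchd4 no longer passed without the second 5-day run (-0.90) or the second 3-week run (-1.15).

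The 12 gene ends with the largest increases rested on fewer fragments, and with the 5-day input deciding which gene ends were compared, only 3 of them (Spry2, Vmn1r137 and Vmn1r143) entered, against 10 of the 12 with the largest decreases. Spry2, which encodes a feedback inhibitor of receptor tyrosine kinase signalling, rose from 76 to 86 distinct fragments in the smaller 3-week library (log2 change 1.30, interval 0.84 to 1.77), and Csta2 from 38 to 54 (1.62, 1.00 to 2.27, but 0.28 without the second 3-week run). The vomeronasal receptor genes Vmn2r42 (1.70), Vmn1r137 (1.64), Vmn1r143 (1.46), Vmn2r32 (1.44) and Vmn1r159 (1.29), the olfactory receptor gene Olfr1112 (1.30) and Btbd35f29 (1.68), Gimd1 (1.59), Crisp1 (1.57) and Fam205a2 (1.47) held 10 to 32 fragments at 5 days. Vmn2r42 was at 0.01 in a 1-kb window and Crisp1 at 0.31. Without the second 3-week run Vmn1r137 (0.58), Vmn1r143 (0.60), Vmn1r159 (0.68) and Btbd35f29 (1.22) no longer passed, without the first Vmn2r32 (0.85) and Fam205a2 (0.79), and without the second 5-day run Btbd35f29 (1.21) and Olfr1112 (1.20). Several of them belong to large gene families, and whether their reads can be placed uniquely was not tested. In all, 59 of 7243 gene ends enriched on average over the stages rose and 68 fell, by the rule of a 2-fold difference with an interval excluding 0. With the 5-day input for both stages, 30 rose and 113 fell. The median change of all 7243 was -0.22, and relative to that median 119 were higher and 22 lower.

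Among genes fixed beforehand, Bach2 (log2 change -0.88, interval -1.30 to -0.49), Men1 (-0.60, -1.06 to -0.18) and Tbx21 (-0.57, -0.89 to -0.27) were lower in 3-week cells without reaching 2-fold. Cdkn2c (0.54, 0.34 to 0.73) and Cdkn2a (0.43, 0.09 to 0.77) were higher without reaching it. At the gene ends of Gata3 (0.22, -0.02 to 0.46), Il4 (-0.12, -0.49 to 0.22), Il5 (0.26, -0.11 to 0.61) and Il13 (0.01, -0.40 to 0.40) the intervals included 0. Men1 and Il13 lay outside the comparison of 7243 gene ends, and their values are given because they were fixed by name. Relative to the median of all gene ends, Gata3 (0.44, 0.20 to 0.68) and Il5 (0.47, 0.11 to 0.82) were higher with intervals excluding 0, and the interval of Men1 (-0.39, -0.84 to 0.03) included 0, so these comparisons depend on the scaling.

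Group medians are given relative to the median of all gene ends, and single genes as log2 changes. By group, T cell receptor signalling stood lowest against random lists matched on signal, with a median of -0.31 (percentile 0) and 19 of 22 members below the median of all gene ends. Naive and memory T cell genes had a median of -0.33 (percentile 0.02), with 15 of 17 below. Another 10 members did not enter the comparison, because their log2 fold over the inputs averaged below 1, and they include Tcf7 (-2.02) and Foxp1 (-1.29). Th2 transcription factors had -0.30 (0.05), with 13 of 18 below, Prdm1 at -0.95 and Nfatc1 at -0.81, while Pparg, a nuclear receptor used by Th2 cells, rose by a log2 change of 1.18. Th17, Tfh and Treg genes had -0.22 (2.02), with 10 of 11 below and Il2rb at -0.83. These 4 medians lay below the middle 95% of random lists. Over all gene ends past the filter on low counts, a comparison chosen after the data were seen, the medians were -0.45 for all 27 naive and memory T cell genes (percentile 0), -0.39 for T cell receptor signalling (0) and -0.38 for Th2 transcription factors (0.01), while Th17, Tfh and Treg genes were inside the random range (-0.16, 7.03).

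The other groups lay inside that range at gene ends. Their medians were 0.19 for Th2 cytokines and effectors (percentile 97.2), 0.14 for Th1 and cytotoxic genes (94.2), 0.22 for senescence factors (91.4), 0.19 for Menin and MLL targets (86.9), -0.04 for Trithorax genes (49.7), -0.03 for cell cycle genes (48.7), -0.13 for Polycomb genes (12.8), -0.13 for apoptosis genes (11.6) and -0.12 for ribosomal proteins (5.06). Over all gene ends, Th1 and cytotoxic genes (0.13, 98.5) lay above the range and ribosomal proteins (-0.18, 1.29) below it. Pcgf5, a Polycomb gene, fell by 1.17 on the log2 scale. Of 4 CD8 T, NK and innate lymphoid cell markers in the comparison, too few for a median, Klrk1 rose (1.05), and Klra8 (1.00), Klrg1 (0.92) and Klra7 (0.11) did not pass. B cell, myeloid and other tissue markers had 1, 3 and 1 members in the comparison.

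The same comparison was made over 5123 gene spans holding 5 or more enriched windows, a step chosen after the broad runs had been seen. The largest decreases were among genes of naive and memory T cells. The spans of Tcf7 (log2 change -1.86, interval -2.02 to -1.70), which encodes the stem-like T cell factor TCF-1, and of Foxp1 (-1.41, -1.44 to -1.38), a factor of T cell quiescence, lost nearly all enriched windows, from 11 to 0 and from 232 to 13. Bach2 (-1.18) and Igfbp4 (-1.07) fell too, and the group's median relative to all spans was -0.61, with 18 of 20 members below the median of all spans and none of 10000 random lists as low. Bach2 (chromosome 4, 32238413 to 32586109) carried 48986 fragments and 267 enriched windows at 5 days, and 9956 fragments and 56 enriched windows at 3 weeks. These fragment counts are not scaled, and the 3-week library was smaller, so the log2 change of -1.18 gives the size of the difference. The 3-week window calls rest on the uneven 3-week input.

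**Figure D3:**
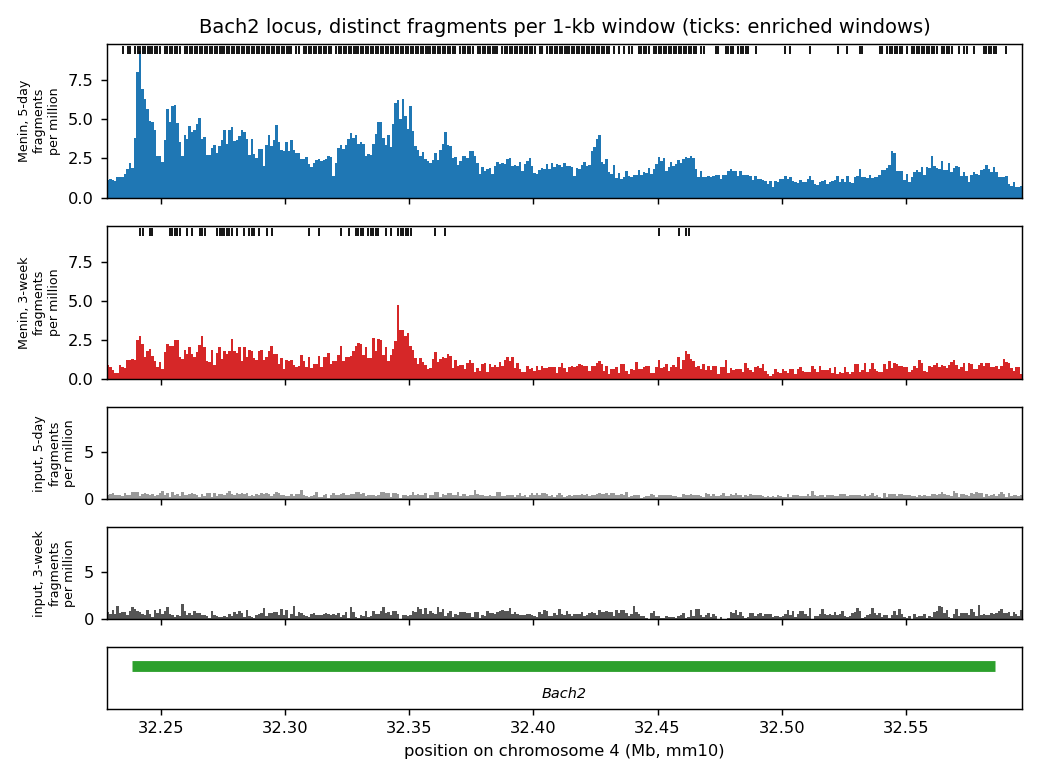
Distinct Menin and input fragments in 1-kb windows, scaled to the same library depth (vertical axes) along the Bach2 locus on chromosome 4 (horizontal axis, Mb, mm10), with the gene span in green and ticks above enriched windows. Over the gene span, 267 windows were enriched at 5 days and 56 at 3 weeks.

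Outside that group, the spans of Slamf6 (-1.19), Trib2 (-1.14), Igsf23 (-1.12), Slamf7 (-1.09), Btg1 (-1.08), Pcgf5 (-1.06), Stat4 (-1.05; 67 to 9 enriched windows), Rab3ip (-1.03), Nfkbil1 (-1.03) and Dusp10 (-1.01) fell. Stat4 transmits IL-12 signals in Th1 cells. The spans of Slc17a6 (1.66, interval 1.53 to 1.78), which encodes a vesicular glutamate transporter, the NK receptor genes Klrc1 (1.21) and Klrc2 (1.20), Depdc1a (1.13; 11 to 31 enriched windows), Inhba (1.09), which encodes the activin A subunit, and Hao1 (1.01) rose. Hao1 did not reach 2-fold without the first 5-day run (0.95), nor did Rab3ip (-0.98), Nfkbil1 (-0.96) and Dusp10 (-0.95) without the second 3-week run. In all 6 spans rose and 16 fell, around a median of -0.17. Relative to that median 11 were higher and 5 lower.

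**Figure D4:**
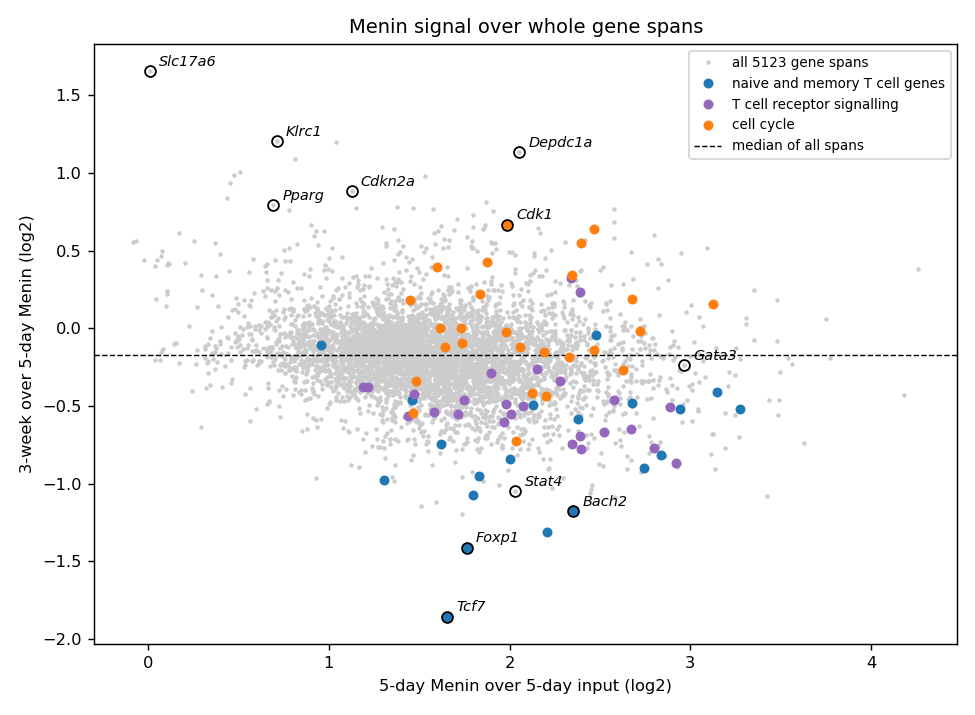
Each point is 1 of 5123 gene spans, placed by 5-day Menin over 5-day input (horizontal axis, log2) and by the change from 5-day to 3-week Menin (vertical axis, log2), with 3 gene groups in colour, named genes circled and the median of all spans at -0.17 as a dashed line. Tcf7, Foxp1 and Bach2 lie low among the naive and memory T cell genes, and Cdk1 lies at 0.67 among the cell cycle genes.

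Over gene spans, with medians relative to all spans and single genes as log2 changes, T cell receptor signalling had a median of -0.33, with 23 of 25 members below the median of all spans, none of 10000 random lists as low, and Cd247 (-0.87), Cd6 (-0.78) and Cd5 (-0.75) among the lowest. Th2 transcription factors had -0.25 (percentile 0.02), with 15 of 18 below, Ets1 at -0.73, Gata3 at -0.24 (-0.06 relative to all spans) and Pparg at 0.79 with 0 enriched windows at 5 days and 39 at 3 weeks. Apoptosis and survival genes had -0.17 (1.76), with Fas at -0.72 and Bcl2l11 at -0.59. Cell cycle genes had 0.15 (99.9), with 7 of 26 members below the median of all spans, the mitotic genes Cdk1 (0.67), Ccnb1 (0.64) and Mki67 (0.55) highest, and Ccnd3 (-0.72) and Ccnd2 (-0.54) lowest. The median at gene ends of cell cycle genes was inside the random range.

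Th2 cytokines and effectors had 0.12 over spans (percentile 96.9, and 98.4 among lists matched on the ratio of the inputs too; Cxcr6 0.50, Il10 0.36, Il4ra -0.61), Menin and MLL targets 0.21 (96.6; Cdkn2a 0.88), Trithorax genes 0.02 (55.9), Polycomb genes -0.02 (37.6), Th17, Tfh and Treg genes -0.09 (24.0), Th1 and cytotoxic genes -0.13 (10.2) and ribosomal proteins -0.21 (9.72). In the Th17, Tfh and Treg group, Tigit went from 0 to 11 enriched windows, but its span changed by only 0.26 (interval 0.15 to 0.36). Those window counts rest on a threshold over each stage's own input. The remaining groups had 3 or fewer spans in the comparison.

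**Figure D5:**
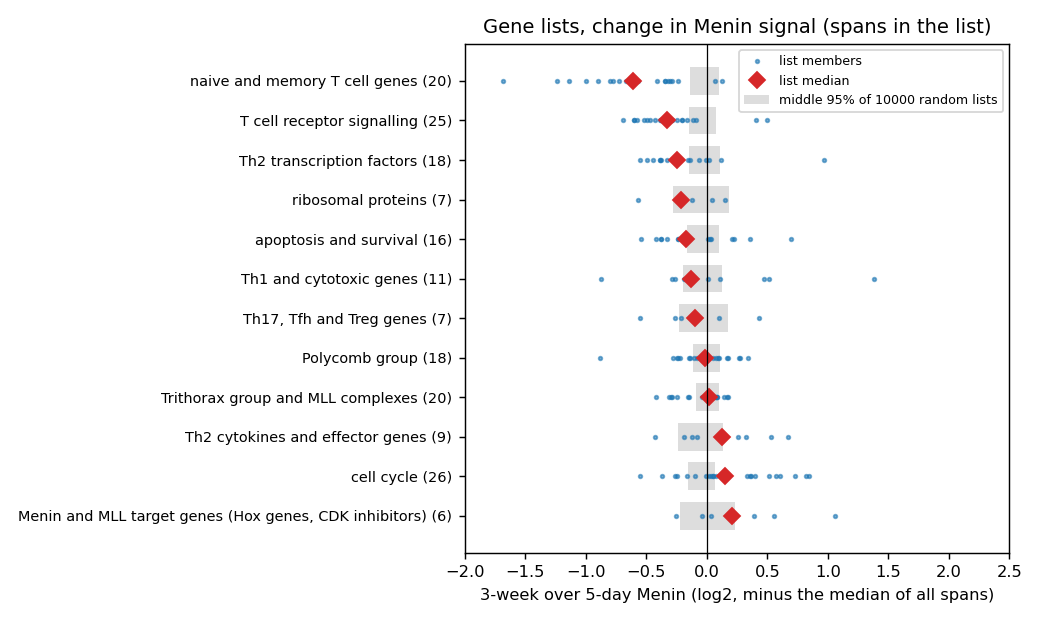
Log2 change from 5-day to 3-week Menin over gene spans, minus the median of all spans (horizontal axis), for members (blue points) and medians (red diamonds) of 12 gene groups, with the number of spans in brackets and grey bars for the middle 95% of 10000 random lists matched on signal. Medians of naive and memory T cell genes (-0.61), T cell receptor signalling (-0.33), Th2 transcription factors (-0.25) and apoptosis genes (-0.17) lie below the bars, and that of cell cycle genes (0.15) lies above.

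At single 1-kb windows, the largest decreases lay inside Ncoa7 (chromosome 10, 30652001 to 30653000; log2 change -3.52, interval -6.04 to -2.14), Nsg2 (-3.42, -5.94 to -2.03), Tcf7 (-3.25 and -3.15 at 2 windows) and Foxp1 (-3.09, -5.16 to -1.84). The largest increases lay in 3 windows at Slc17a6 (3.03, 2.88 and 2.88) and in windows outside genes whose nearest protein-coding genes were Ndst3, 290827 bp away (3.02, 2.00 to 4.32), and Lsm8, 38635 bp away (2.78, 1.89 to 3.84). Of 101434 windows enriched in either stage, 1484 rose and 6256 fell around a median of -0.22. Relative to that median 3211 were higher and 2942 lower.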

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

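All tests in this part were chosen after the results they bear on were seen.

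The 2 Menin samples of each stage stood out because they shared fragment positions far above the level in other pairs, at 36.5% of the first sample's positions in 5-day and 72.8% in 3-week cells. Shared hot spots in separate libraries are argued against by windows with few fragments, where 34.7% and 72.1% of positions were still shared, against 0.580% and 0.478% by chance. Resequencing of 1 amplified library remains a candidate explanation: the number of molecules estimated from shared positions was 1.19 times (5-day) and 1.09 times (3-week) that estimated from copies within the first sample alone. No biological explanation was tested.

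The lower 3-week Menin signal over naive and memory T cell genes, seen at Tcf7, Foxp1 and Bach2, was weighed against 3 technical explanations. Leaving out copies in a less complex 3-week library is argued against as the whole cause, since the group's median relative to all spans was -0.65 with copies counted. The bias that separates the 2 inputs and a weaker 3-week library as a whole are argued against in the same way, since 0 of 10000 random lists matched on signal, and 0 of those matched on signal and on the ratio of the inputs, were as low. In the same comparison the neighbouring NK receptor spans Klrc1 (1.21) and Klrc2 (1.20) rose. Over all gene ends, 14 markers of CD8 T, NK and innate lymphoid cells had a median of 0.14 (percentile 58.1). Only 3 of these 14 were enriched at 5 days and 10 lay outside the comparison of gene ends, so that median mostly covers ends with little Menin. The 1 span of this group in the comparison, Klrk1, was higher at 3 weeks (0.98) without reaching 2-fold. Base composition, a shift in the mix of cells and the culture stage itself stay open and untested, with 1 library counted per stage.

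The 3-week input was uneven, with 7.30% of 1-kb windows empty. A difference in DNA content between the cells is argued against as the main cause. Over 1-Mb bins the 3-week to 5-day ratios of Menin and of input correlated negatively (Pearson r = -0.54, Spearman rho = -0.62, across bins, which are not independent), where gained or lost DNA would move both ratios together. A correlation over all bins cannot exclude gains or losses in single regions. Bins with a lower input ratio also tended to have a higher Menin ratio. Base composition bias in preparing that input cannot be told apart from other causes of its 7.30% empty windows, because no genome sequence was used here. No biological explanation was tested.

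At 3 of the named gene spans Menin lay above input in 5-day cells and below input in 3-week cells, with both 95% intervals excluding equality and the difference itself not tested. The log2 folds over input were 1.66 and -0.85 at Tcf7, 1.51 and -0.22 at Trib2, and 1.59 and -0.35 at Igsf23, while Igfbp4 (1.80 and -0.23) had opposite signs with a 3-week interval that did not exclude equality. Over the 5-day input the 3-week values were -0.20, 0.37 and 0.48, so that the sign at Trib2 and Igsf23 depends on the input used.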

How the results depend on the processing

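The alternatives that use the 5-day input, thinning, changes relative to the median, gene spans, edgeR without a block or lists over all gene ends were chosen after the data were seen. Across 98 results, 607 of 669 alternative values stayed on their side of the threshold or, for counts, within 1.5 times whatever their split by direction. Within gene ends or within spans, no called single-gene value changed sign. Nor did the list medians followed there, of naive and memory T cell genes, T cell receptor signalling and Th2 transcription factors, and of cell cycle genes over spans. Between gene ends and spans, medians differed in sign for cell cycle (-0.03 and 0.15), Th1 and cytotoxic (0.14 and -0.13) and Trithorax genes (-0.04 and 0.02). The balance of higher and lower calls did turn. Enriched gene ends moved to 3450 in 5-day and 1275 in 3-week cells at 4-fold, and to 8621 in 3-week cells over the 5-day input. The 127 changed gene ends became 64 with scaling by total fragments (43 higher, 21 lower), 203 with 1-kb windows (78, 125), 921 over all ends past the filter on low counts and 929 with no filter, because more ends were tested, and 3371 for change in Menin minus change in input. Their split of 59 higher and 68 lower became 122 and 22 with TMM on gene ends, 119 and 22 relative to the median, 30 and 113 with the 5-day input and 47 and 89 after thinning, so the balance of directions depends on the scaling for the former pair of settings and on the gene ends compared or the depth for the latter. Which gene ends were called moved too: 48 of the 127 were called with total scaling, 54 with 1-kb windows and 71 to 96 with 1 run left out.

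With the 2 runs taken as replicates, edgeR called 3666 gene ends and 49498 windows, DESeq2 768 (367 higher, 401 lower) and 15874, at an adjusted p under 0.05 with no minimum fold. With the replicate number as a block, edgeR called 3586 gene ends (458 higher, 3128 lower) and 49507 windows. Nothing in the labels ties a number to a shared culture, and these counts rest on a spread between samples that share many fragments. Enriched windows numbered 23843 and 15600 under the stricter threshold, with 10843 shared, and 203688 and 147272 under the looser one, with 103647 shared. Changed windows were split 1484 higher and 6256 lower, 2266 and 4168 with total scaling, 3239 and 2929 with TMM on enriched windows, and 8160 and 7714 by DESeq2. Changed gene spans were split 9 higher and 7 lower with total scaling, against 6 and 16. Lists with a share in the highest 2.5% in 3-week cells numbered 2 at 4-fold and 10 over the 5-day input, against 5. Where no cause is given, the cause was not tested. The most upstream start site, which needs strand, and the planned list tests with an estimated correlation or a replicate block, which need replicates, were not run.

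Of 511 values of named genes, 471 stayed, 30 no longer passed and 10 moved. Calls lost most often were on few fragments, at vomeronasal receptor genes, Btbd35f29, Olfr1112 and Ptchd4. Csta2 fell to 0.28 without the second 3-week run, and Vmn2r42 to 0.01 in a 1-kb window. Leaving out a run kept the medians of naive and memory T cell genes between -0.64 and -0.61 over gene spans and between -0.38 and -0.29 at gene ends. TMM on gene ends shifts all ends alike, so it tests nothing for medians relative to all ends. Depth limits gene ends, with medians of 40 fragments in 3-week Menin and 29 in each input.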

Other observations

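The tests and genes in this part were chosen after interferon-responsive genes had been seen among the highest 5-day signals. Interferon-stimulated genes, which antiviral signalling induces, carried strong Menin signal in 5-day Th2 cells. Of 49 tested genes in a list drawn up after 8 of them had been seen, 43 were enriched (87.8%), with a median log2 fold over input of 2.68. High values were those of Herc6 (4.14), Parp14 (4.04), Irgm1 (3.93), Parp9 (3.78), Tap2 (3.75) and Psmb8 (3.62). Ifi44 (0.20) and Oas1a (-0.02) were lowest.

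The hypothesis that Menin signal at these genes stands above that of other genes in 5-day cells was tested without the 8 genes that prompted it. The median of the other 41 was 2.52, at percentile 100 of 10000 random lists matched on the 5-day input, whose middle 95% ran from 0.85 to 1.56. Of the 41, 35 were enriched, so the signal may extend over the class in this library. The random lists came from all tested genes. Medians above 1.56 were also found for T cell receptor signalling (2.21), cell cycle genes (2.19), Th2 transcription factors (2.06) and naive and memory T cell genes (2.05). Apoptosis genes (1.95), ribosomal proteins (1.85), Polycomb genes (1.83) and Trithorax genes (1.79) lay above it too. The remaining groups, Th1 and cytotoxic genes (1.34) among them, lay below it. High signal was thus not particular to interferon-stimulated genes. In 3-week cells, over the 5-day input, their median was 1.95 and 32 were enriched. Their change over 23 gene spans, relative to all spans, had a median of -0.18 (percentile 0.445). Some of these genes sit in clusters of related copies, the Gbp genes among them, and some are neighbours whose windows overlap. Whether their reads can be placed uniquely was not tested.

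Alcam, which encodes an adhesion molecule, and the mitotic kinesin gene Kif11 were among the longest 3-week runs with higher signal than at 5 days. A 30-kb run inside Alcam (chromosome 16, 52394001 to 52424000) had 1 enriched window at 5 days and 30 at 3 weeks, with a log2 change of 1.32. A 33-kb run at Kif11 was enriched throughout at both stages, with a log2 change of 0.72. The span of Klrk1, which encodes the NK receptor NKG2D, went from 0 to 10 enriched windows, with a log2 change of 0.98 that did not reach 2-fold.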
